A study of Caenorhabditis elegans with 2 samples.

How the data were processed

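The measurement was chromatin immunoprecipitation with sequencing (ChIP-seq) of NHR-2, a nuclear hormone receptor, in whole Caenorhabditis elegans embryos of mixed stages and both sexes. Per the labels, the animals were of strain OP99, which carries an integrated transgene, wgIs99, in an unc-119 mutant background. The labels describe the immunoprecipitated protein as an eGFP fusion of NHR-2 in 1 field and name nhr-2 itself as the antibody target in another, so the antibody used is not settled by them. There were 2 libraries, given by the labels as biological replicates 1 and 2 of a single group. A control library is named in the labels and was not analysed here, and no library of animals without the transgene was analysed here. With 1 group, no comparison between groups of samples could be made; every comparison is within the genome, between regions, genes or words.

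The authors deposited 4 region lists on each of 2 genome builds. A candidate list for each replicate and a candidate list of the series held 30000 regions each. A list of peaks was thresholded by the irreproducible discovery rate (IDR), per the texts deposited with the libraries. IDR is a method that compares the ranks of regions in replicates. Those texts state that the candidate lists came from the ChIP alignments and a control, and that the thresholded list came from the series list and both replicate lists. Each region had a signal value in the deposited lists, the authors' enrichment score, which is never negative and was used to describe, rank and filter regions. Each region also had a −log10 q value in the deposited lists, which was at its ceiling for 1832 of the 1861 thresholded peaks and was not used for ranking. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Read numbers were not given in the lists, so sequencing depth is unknown, and signal was not compared as a level between lists. Every candidate list ended at the same number of regions, so its length does not measure how much of the genome was enriched. All 1861 thresholded peaks were in the series candidate list, and they were its 1861 strongest regions.

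Lists on build ce11 were used for everything that needs an annotation, because all region ends lay within the chromosome lengths of WBcel235, the assembly of that build. The ce10 lists were used only for numbers of regions, chromosome shares and replicate overlap, and no coordinate was moved between builds. Genes were the 19973 protein-coding genes on chromosomes I to V and X in Ensembl release 115. Coordinates are 1-based. Mitochondrial peaks were kept out of every annotation, gene and word comparison.

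A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a gene, and a gene was called bound when a thresholded summit lay in its window. A summit counted for every gene whose window held it. Summits were otherwise classed in the order RNA gene, exon, intron, pseudogene and intergenic. The reference for class shares was 1000 circular shifts of the summits along each chromosome, which keep their spacing; the smallest one-sided p these can give is 0.000999. Replicate overlap was the share of the 1861 strongest candidate regions of a replicate that shared 1 bp or more with the 1861 strongest of the other, against 1000 circular shifts. Genes on X were compared with those on chromosomes I to V by two-sided Fisher exact tests. For 21 gene lists the share of bound members was compared with all other protein-coding genes by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over the lists, and a list was called at an adjusted p under 0.05. Of the names in the lists, 4 matched no annotated gene. For words, the presence of each of 2080 6-base words on either strand within 75 bp of the summit was compared with a window of equal width 400 bp to its left or right, the side being drawn at random, by two-sided exact McNemar tests with Benjamini-Hochberg adjustment. There were 7 planned words, reported whatever their test. Confidence intervals are 95% exact Clopper-Pearson intervals; they cover counting error over peaks or genes and leave out differences between animals.

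The lists, windows, tests, planned words and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes the gene with the nearest 5′ end within 5000 bp of each of the 20 strongest peaks that had a candidate region in both replicates, up to 4 bound members of each list with the highest signal, and nhr-2 and unc-119 whatever their values. Genes named outside this rule are marked as chosen after their values were seen; they include genes that hold 1 of the strongest peaks and the bound cell cycle genes beyond the first 4. The alternatives covered the build, each replicate alone, stricter thresholds, removal of the strongest peaks, merged peaks, narrower and wider promoter windows, nearest-gene assignment, other backgrounds, a shift test for lists, removal of the transgene locus, other overlap rules, and other windows and controls for words. Controls matched for GC content, the central part of each chromosome, peaks with or without the word AGGTCA, and transcript 5′ ends were added after seeing the data.

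Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The statistics were tested on simulated data. With 1861 summits placed at random, 0 of 21 lists and 0 of 2080 words were called. This placement was uniform along the chromosomes, so it favoured neither open chromatin nor sequence richer in G and C than its flanks. It cannot show how many calls such differences alone would give. With 40 ribosomal protein genes given a summit among many random promoters, 1 of 21 lists was called, the planted one. With AGGTCA written into windows until 22.2% held it, 22.1% were recovered and the word ranked 1 among 2080. With 60.0% of 1861 regions shared between simulated replicates, 60.6% were recovered.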

Results

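ChIP-seq of NHR-2 was carried out in mixed-stage embryos of C. elegans, with 2 biological replicates. NHR-2 is a nuclear hormone receptor, a zinc-finger transcription factor of the family that includes the vertebrate steroid and thyroid hormone receptors. The thresholded list held 1861 peaks, 1843 on the nuclear chromosomes and 18 on the mitochondrial chromosome. Peaks had a median width of 380 bp and covered 633 kb, or 0.631% of the genome. The signal, which is the authors' own score for each region, ran from 51.6 to 2371 with a median of 83.3. Sequencing depth is unknown, since the lists give no read numbers.

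The strongest nuclear peaks in the genome lay at nhr-2 itself, on chromosome I from 5818474 to 5821134 on the minus strand (ce11). A summit at 5822750, in intergenic sequence 1616 bp upstream of the nhr-2 5′ end, had a signal of 2151. The next lay at 5820614 in an nhr-2 intron, with a signal of 1638, and at 5821303 in the nhr-2 promoter, 169 bp upstream of the 5′ end, with a signal of 1111. These ranked 2, 3 and 5 among all thresholded peaks. In replicate 1 they ranked 1, 3 and 4, and in replicate 2 they ranked 2, 4 and 6. The strongest nuclear peak elsewhere had a signal of 806. In all, 5 thresholded peaks lay within 20 kb of nhr-2, and 4 of them held the word AGGTCA, the core of many nuclear receptor binding sites, within 75 bp of the summit. The transgene adds copies of nhr-2 sequence to the genome, so signal at this locus may come from native and transgene copies together. The labels do not give the extent of the copied sequence, so it is not known which of these peaks it covers. The unc-119 gene, on chromosome III from 10902641 to 10908935, had 0 thresholded peaks within 5 kb, and its strongest series candidate region had a signal of 32.2.

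**Figure D1:**
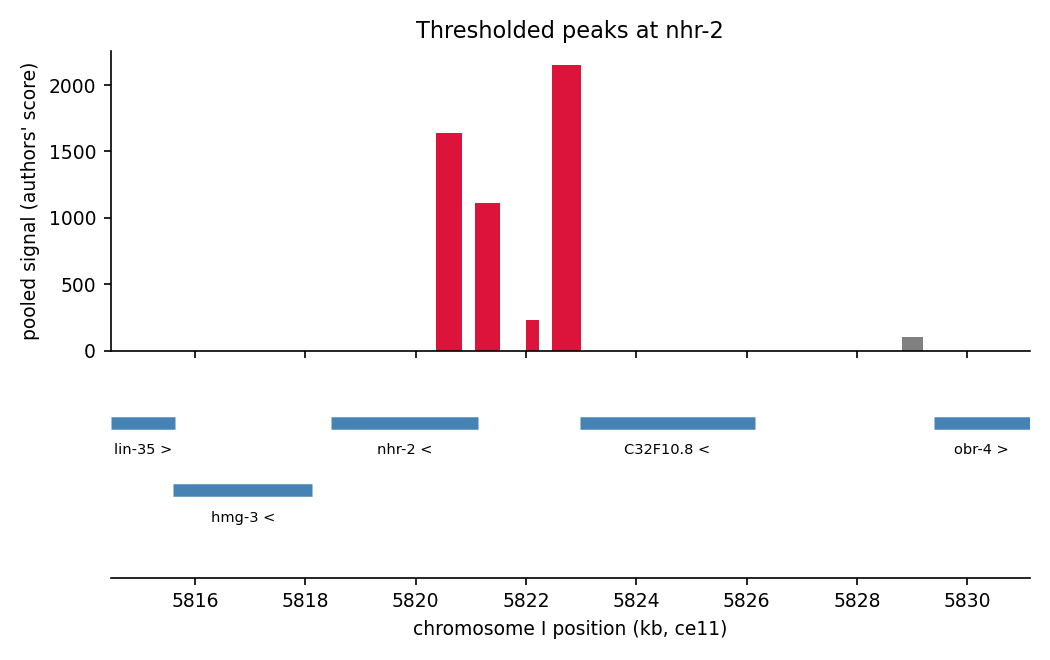
Thresholded peaks at nhr-2 on chromosome I, with position in kb (ce11) on the horizontal axis and the authors' pooled signal on the vertical axis. Each bar spans a peak, red with AGGTCA within 75 bp of the summit and grey without, and the blue bars below are protein-coding genes with their strand; 4 of the 5 peaks are red, and the tallest reaches 2151.

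Of the 20 strongest peaks, 5 were mitochondrial and 3 were at nhr-2; the other 12 lay elsewhere in the nuclear genome. A peak of signal 737 lay 1026 bp upstream of ces-2, a bZIP factor that specifies programmed cell death, with its summit at 14960471 on chromosome I. A peak of signal 574 lay 1723 bp upstream of cyd-1, which encodes cyclin D, at 12978868 on chromosome II. A peak of signal 642 lay 3215 bp upstream of egl-46, a zinc-finger factor of neuronal differentiation, at 6684788 on chromosome V. A peak of signal 806 lay within an intron of zfp-1, a chromatin factor related to mammalian AF10, at 8795849 on chromosome III; the nearest 5′ end was that of ztf-1, 3498 bp away. Further intronic peaks were in vab-1, an Eph receptor, with a signal of 572, and in mnk-1, a protein kinase, with a signal of 566. An exonic peak in tir-1, a TIR-domain adaptor of signalling, had a signal of 726 and had rpl-3 as its nearest 5′ end, 4098 bp away. The genes named here as holding a peak, zfp-1, vab-1, mnk-1 and tir-1, were chosen after their values were seen. The other nearest genes were del-4 with a signal of 805, hsp-12.1 with 786, adah-1 with 733, fbxl-5 with 628 and cki-1 with 615. AGGTCA lay at the summits near hsp-12.1, ces-2 and cki-1 and at none of the remaining 9.

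Whether the replicates marked the same places was asked first. They shared most of their strongest regions: the peak near ces-2 ranked 9 and 15 in replicates 1 and 2, that near cyd-1 14 and 26, and that near cki-1 17 in both. Of the 1861 strongest candidate regions of replicate 1, 1291 overlapped those of replicate 2 (69.4%, 95% confidence interval 67.2 to 71.5%), against a mean of 2.17% and a maximum of 3.33% in 1000 circular shifts (p = 0.000999, one-sided permutation by shifts, the smallest these can give). In the other direction the share was 69.1%. Of the thresholded peaks, 87.8% overlapped a region among the 3000 strongest of both replicates, and 13 had no candidate region in at least 1 replicate. Of these peaks, 68.6% overlapped a region among the 1861 strongest of both replicates. The lowest ranks were 27290 in replicate 1 and 28913 in replicate 2. The list was thresholded by comparing ranks in the replicates. It held the 1861 strongest regions of the series list, whose signal draws on both replicates. The 87.8% and the 68.6% are therefore no separate test of agreement. Across 1830 nuclear peaks, which are not independent replicates, the signals of the 2 replicates had a Spearman correlation of 0.639 and a Pearson correlation of 0.736 on the log2 scale. The Spearman correlation was 0.690 over the 915 strongest and −0.295 over the 915 weaker. The split was by pooled signal, which draws on both replicates. Among weaker peaks of similar pooled signal, a higher value in 1 replicate therefore goes with a lower value in the other. The negative value does not measure disagreement, and the split cannot show whether the agreement rested on the stronger peaks. The order of the weaker peaks remains without support here.

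**Figure D2:**
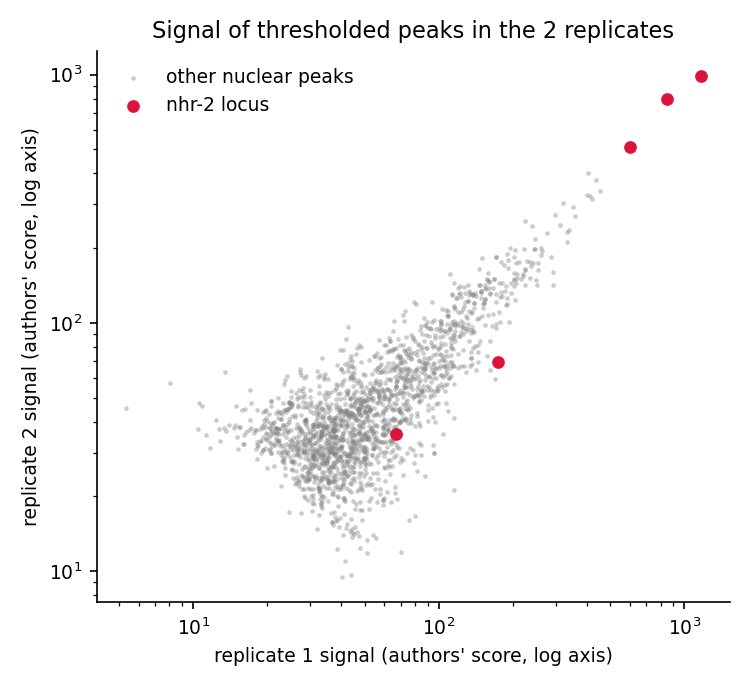
Signal of each nuclear thresholded peak in replicate 1 (horizontal) and replicate 2 (vertical), both the authors' scores on log axes. Of the 1830 points, red marks the 5 peaks at the nhr-2 locus, of which 3 lie above all other peaks in both replicates, and grey the rest.

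Peaks lay in promoter windows and intergenic sequence more often than shifted summits, and in exons and introns less often. Of 1843 nuclear summits, 664 (36%, 33.8 to 38.3%) were in promoter windows, 468 (25%) in introns, 536 (29.1%) in intergenic sequence and 50 (2.71%) in exons. Promoters held 1.72 times the share given by shifted summits, which was 21%, and intergenic sequence 1.33 times theirs, which was 21.9%. Exons held 0.118 times the shifted share of 23.0% and introns 0.838 times that of 30.3% (p = 0.000999 for each of the 4, one-sided permutation by 1000 circular shifts). RNA genes outside promoter windows held 124 summits (6.73%, 5.63 to 7.97%), 4.74 times the shifted share of 1.42% (permutation p = 0.000999). The strongest peak near cki-1 had its summit in T05A6.8, a noncoding RNA gene named after its values were seen. The median distance from a summit to the nearest protein-coding 5′ end was 1419 bp, and 15.8% lay beyond 5000 bp. In total 831 protein-coding genes (4.16%) had a summit in the promoter window. Other candidate regions outside the thresholded list were in promoters in 26.4% of cases and in RNA genes in 2.01%. The promoter excess was smaller among the strongest peaks. With the strongest 930 peaks, 28.3% of nuclear summits were in promoters, 1.35 times the shifted share of 20.9%. Promoter summits had a median signal of 73.6, against 91.7 in introns and 90.8 in intergenic sequence.

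The X chromosome carried more peaks than the autosomes. It had 24.7 peaks per Mb, against 17 on chromosomes I to V, and 175 of its 2731 genes (6.41%, 5.52 to 7.39%) were bound, against 656 of 17242 autosomal genes (3.80%, 3.52 to 4.10%; odds ratio 1.73, p = 2.40e-09, two-sided Fisher exact test). The X-linked bound genes included sex-1, a nuclear hormone receptor that acts in counting X chromosomes, with a signal of 118, and ceh-39, a ONECUT homeodomain factor with a related role, with a signal of 69.3. They also included sdc-1, a regulator of sex determination and dosage compensation, with a signal of 69.2, and syd-2, a liprin of synapse assembly, with a signal of 463. Among the autosomes, chromosome V had the lowest share, 113 of 4994 genes (2.26%, odds ratio against all other chromosomes 0.460, Fisher exact adjusted p = 1.37e-15). Chromosome IV had 3.05%. Chromosomes I and III had 5.66% (4.85 to 6.57%) and 5.61% (4.76 to 6.55%), intervals that overlap that of X. Their densities were 20.4 and 21.3 peaks per Mb. Of the candidate regions on X, 8.47% were in the thresholded list, against 5.66% on the autosomes (odds ratio 1.54, p = 2.04e-13, two-sided Fisher exact test).

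Which groups of genes carried peaks in their promoters was asked with 21 lists. Heat shock, ribosomal protein and cell cycle genes had the highest shares. Of 31 cell cycle genes, 10 were bound (32.3%, 16.7 to 51.4%; odds ratio 11.1, adjusted p = 2.06e-06, two-sided Fisher exact test with adjustment over 21 lists). The strongest were cki-1 and cki-2, which encode inhibitors of cyclin-dependent kinases, with signals of 417 and 368, cye-1, which encodes cyclin E, with 354, and fzr-1, an activator of the anaphase-promoting complex, with 281. With replicate 2 alone 8 were bound (odds ratio 7.36), and with the top 10% of peaks by signal left out 6 (odds ratio 5.86); the call was kept in both. The remaining bound members, chosen for naming after their values were seen, were cdc-14, cdk-2, cdk-4, cya-1, lin-23 and mat-1. From the promoter of cki-1 to the 3′ end of cki-2 lay 7 peaks, on chromosome II from 7810811 to 7819709, with signals from 71.1 to 615; 2 held AGGTCA.

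**Figure D3:**
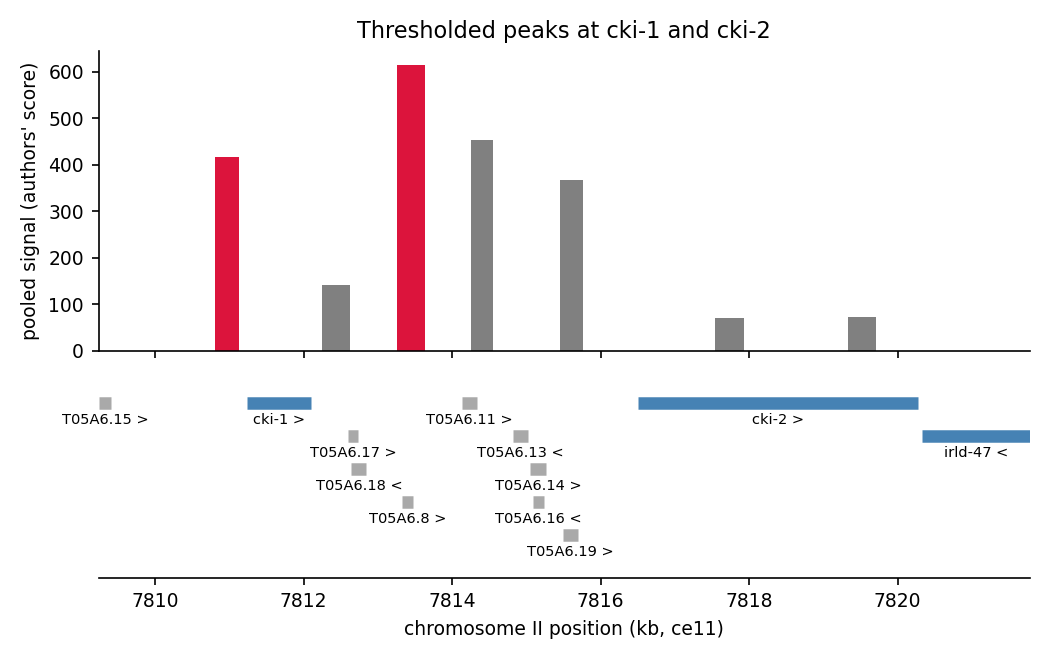
Thresholded peaks at cki-1 and cki-2 on chromosome II, with position in kb (ce11) on the horizontal axis and the authors' pooled signal on the vertical axis. Bars are red with AGGTCA within 75 bp of the summit and grey without; below, blue bars are protein-coding genes and grey bars noncoding RNA genes. The tallest of the 7 peaks, at 615, overlaps T05A6.8 between the 2 genes.

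Ribosomal protein genes were bound in 26 of 80 cases (32.5%, 22.4 to 43.9%; odds ratio 11.4, Fisher exact adjusted p = 8.15e-16). Their signals were moderate: rps-20 had 145, rpl-3 143, rpl-11.2 116 and rps-26 103.7. Of 22 heat shock protein genes, 8 were bound (36.4%, 17.2 to 59.3%; odds ratio 13.3, Fisher exact adjusted p = 8.67e-06). Among them, hsp-110 had a signal of 117, hsp-3, which encodes an endoplasmic reticulum chaperone, 117, hsp-60, which encodes a mitochondrial chaperonin, 97.3, and hsp-1, which encodes a constitutive Hsp70, 77.7. Of 72 histone genes, 12 were bound (16.7%, 8.92 to 27.3%; odds ratio 4.66, Fisher exact adjusted p = 0.000161), through 7 distinct peaks, since neighbouring histone genes such as his-67 and his-68, or his-31 and his-32, share a promoter region. The peak of the former pair had a signal of 187 and that of the latter 134.

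Of 30 Wnt signalling genes, 7 were bound (23.3%, 9.93 to 42.3%; odds ratio 7.06, Fisher exact adjusted p = 0.000648). They included dsh-2 and mig-5, which encode Dishevelled proteins, with signals of 116 and 96.7, mom-5, which encodes a Frizzled receptor, with 102, and sys-1, which encodes a β-catenin, with 67.9. Of 92 homeodomain factors, 11 were bound (12%, 6.12 to 20.4%; odds ratio 3.16, Fisher exact adjusted p = 0.00452). The strongest were ceh-20, of the Pbx class, with a signal of 205, ceh-16, the engrailed gene, with 133, ceh-40 with 127 and ceh-53 with 96.3. This call was lost with replicate 2 alone (odds ratio 1.73, Fisher exact adjusted p = 0.418) and with a narrower promoter window (adjusted p = 0.136).

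Genes of sex determination and dosage compensation were bound in 4 of 21 cases (19%, 5.45 to 41.9%; odds ratio 5.44, Fisher exact adjusted p = 0.0264). These were dpy-27, a condensin subunit of the dosage compensation complex, with a signal of 149, and the X-linked sex-1, ceh-39 and sdc-1. Early embryonic lineage genes were bound in 5 of 40 cases (12.5%, 4.19 to 26.8%; odds ratio 3.30, Fisher exact adjusted p = 0.0464). They were cnd-1, the NeuroD homologue, with a signal of 242, pal-1, the caudal homologue, with 87, sys-1, nob-1, a posterior Hox gene, with 53.9, and ref-1, a bHLH factor, with 52.2. With genes that have any candidate region as the background, the call ended for sex determination (odds ratio 2.33, Fisher exact adjusted p = 0.222) and for the lineage genes (odds ratio 2.91, adjusted p = 0.130). The sex determination call was also lost with the strongest 930 peaks (2 bound, odds ratio 6.74, Fisher exact adjusted p = 0.108), where the excess was no smaller and fewer genes were bound, with the narrower promoter window (odds ratio 3.32, adjusted p = 0.238) and with the wider one (odds ratio 3.73, adjusted p = 0.0580). The lineage call was also lost with replicate 2 alone (odds ratio 1.70, Fisher exact adjusted p = 0.642), with replicate 1 alone (odds ratio 2.06, adjusted p = 0.338), with the strongest 930 peaks (2 bound, odds ratio 3.36, adjusted p = 0.242) and with the narrower window (4 bound, odds ratio 3.51, adjusted p = 0.0895); in the last 2 the excess was no smaller and fewer genes were bound. The lists overlap: the lineage list shared 2 bound members with the homeodomain list and 2 with the bHLH list.

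Chemoreceptor, cuticle collagen and neuropeptide genes were bound less often. Of 1256 chemoreceptor genes, 5 were bound (0.398%, 0.129 to 0.927%; odds ratio 0.0866, Fisher exact adjusted p = 2.43e-16), among them srt-63 with a signal of 97.8 and str-81 with 70.9. Of 174 cuticle collagen genes, only col-38 was bound, with a signal of 87.4 (0.575%; odds ratio 0.132, Fisher exact adjusted p = 0.0264). Of 102 neuropeptide genes, 0 were bound (95% upper limit 3.55%; Fisher exact adjusted p = 0.0464). A circular shift of summits keeps gene clusters together, and takes shifted summits instead of other genes as the reference. Shifted summits lay in promoters less often than the peaks, which lowers the expected counts and makes a depletion harder to call. This test ended the calls for collagens (1 bound against 3.62 expected, adjusted permutation p = 0.411) and neuropeptides (0 against 2.30, adjusted p = 0.329). The call for chemoreceptors was kept (5 against 20.8, a fold of 0.241, adjusted permutation p = 0.00599). The collagen call was also lost with the strongest 930 peaks (odds ratio 0.366), the narrower window (0.180) and the background of genes with a candidate region (0.207), with 1 gene bound in each. With replicate 1 alone the neuropeptide call was lost as well (Fisher exact adjusted p = 0.0727); in all it was lost under 8 of the 11 alternatives set before the data were examined, with 1 gene bound in the wider window (odds ratio 0.156) and 0 in the others.

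The family of NHR-2 itself, 274 nuclear hormone receptor genes, was bound in 11 cases (4.01%, 2.02 to 7.07%; odds ratio 0.963, Fisher exact adjusted p = 1). By circular shift the direction turned, with 4.85 bound members expected from shifted summits, a fold of 2.27 that passed no threshold (adjusted permutation p = 0.0671); all promoters together held 1.72 times their shifted share. Besides nhr-2 and sex-1, the strongest was a peak of signal 152 in the shared promoter region of nhr-152 and nhr-94, with AGGTCA at its summit. The other lists passed no threshold. Of 37 bHLH factors 4 were bound (Fisher exact adjusted p = 0.116), led by cnd-1 and then by hlh-16 with a signal of 148. Body wall muscle genes were bound in 2 of 29 cases, unc-112 and unc-60. A single bound member was found in each of the pharyngeal list (ceh-22), the neuronal list (syd-2), the germline and maternal list (spn-4) and the T-box list (tbx-11). None was bound of 26 intestinal genes, 12 GATA-type factors and 31 major sperm protein genes, for which the 95% upper limits were 13.2%, 26.5% and 11.2%.

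**Figure D4:**
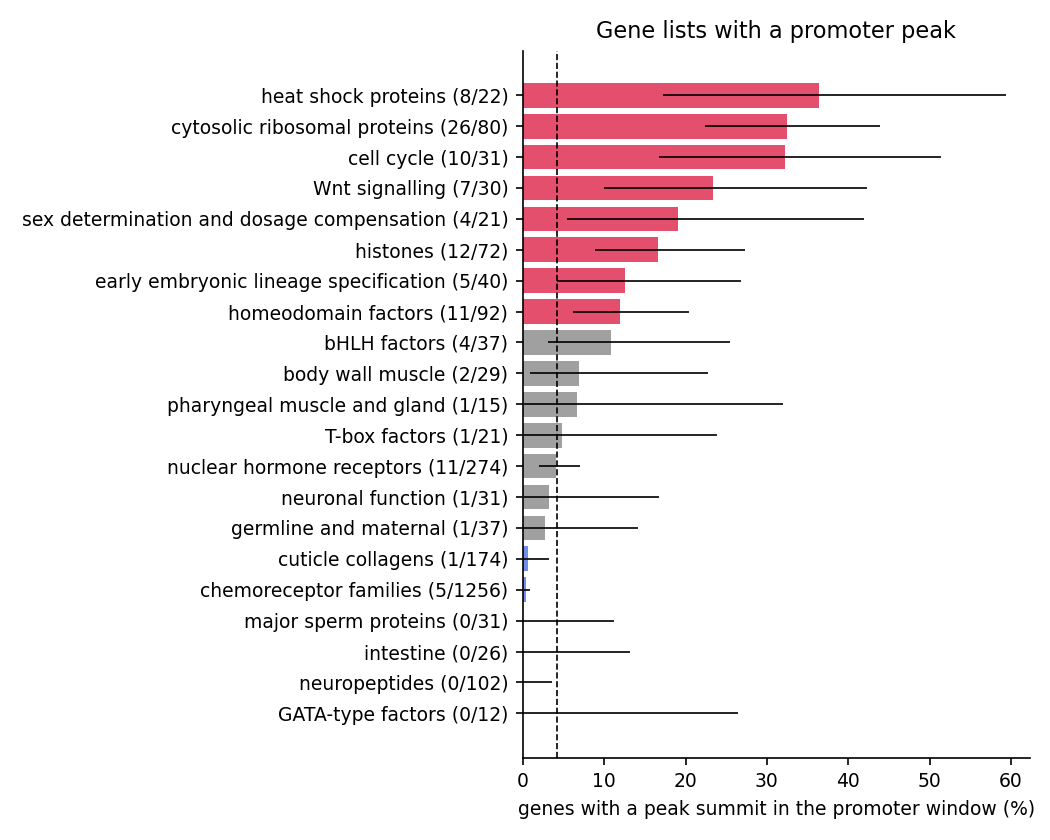
Percentage of the members of each gene list with a peak summit in the promoter window; bars are shares, black lines 95% exact confidence intervals, and the numbers of bound and annotated members follow each name. Red and blue bars mark lists bound more and less often than other genes at an adjusted p under 0.05, grey bars the remaining lists (neuropeptides, at 0 and so without a bar, passed as lower), and the dashed line is the share of all protein-coding genes, 4.16%.

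The sequence under the summits was then examined. The nuclear receptor core word AGGTCA lay within 75 bp of 17.3% of nuclear summits (15.6 to 19.1%), against 3.74% (2.92 to 4.71%) of flanking windows (ratio 4.61, adjusted p = 1.30e-42, two-sided exact McNemar test). GAGAGA was more frequent, in 30% of summits against 8.41% of flanks (exact McNemar adjusted p = 4.70e-58). Among E-box words, CAGGTG lay in 14.4% against 3.58% (exact McNemar adjusted p = 1.23e-31), CAGCTG in 6.35% against 2.60% and CACGTG in 4.88% against 2.17%. AAGTCA, another nuclear receptor core word, was less frequent at summits, 4.07% against 6.24% (exact McNemar adjusted p = 0.00719). The GATA word AGATAA lay in 9.71% of summits and 9.98% of flanks (exact McNemar adjusted p = 0.875).

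Summits were richer in G and C than flanks, 45.4% ± 6.55 against 34.9% ± 7.62 (mean ± SD over 1843 peaks), and 1214 of 2080 words differed, 801 of them higher at summits. Against candidate regions of matched GC content, a control added after seeing the data, 583 words differed and 294 were higher. AGGTCA then had the smallest p among the higher words, at 17.3% against 6.89% (ratio 2.50, adjusted p = 1.04e-19, Fisher exact test), and GGGTCA came next with 12.4% against 4.29%. ACGCAA followed, at 15.3% against 6.29% (ratio 2.43), and TACGCA had a ratio of 2.70, above that of AGGTCA. ACGCAA and TACGCA were chosen after their values were seen. With this control CAGGTG lay in 14.4% against 6.89% (ratio 2.09, Fisher exact adjusted p = 1.35e-11) and GAGAGA in 30% against 21% (ratio 1.43, adjusted p = 2.23e-08). CAGCTG, CACGTG and AAGTCA were no longer called (Fisher exact adjusted p = 0.104, 0.296 and 0.573), and AGATAA was higher, at 9.71% against 6.73% (adjusted p = 0.00695).

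AGGTCA was more frequent at stronger peaks. It lay at 26.2% (22.3 to 30.5%) of the 461 strongest nuclear summits and at 11.1% (8.37 to 14.3%) of the 460 weakest (odds ratio 2.85, p = 3.64e-09, two-sided Fisher exact test). Promoter summits held it in 16.6% of cases and other summits in 17.6% (Fisher exact p = 0.608), and X-linked summits in 18.3% against 16.9% on the autosomes.

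**Figure D5:**
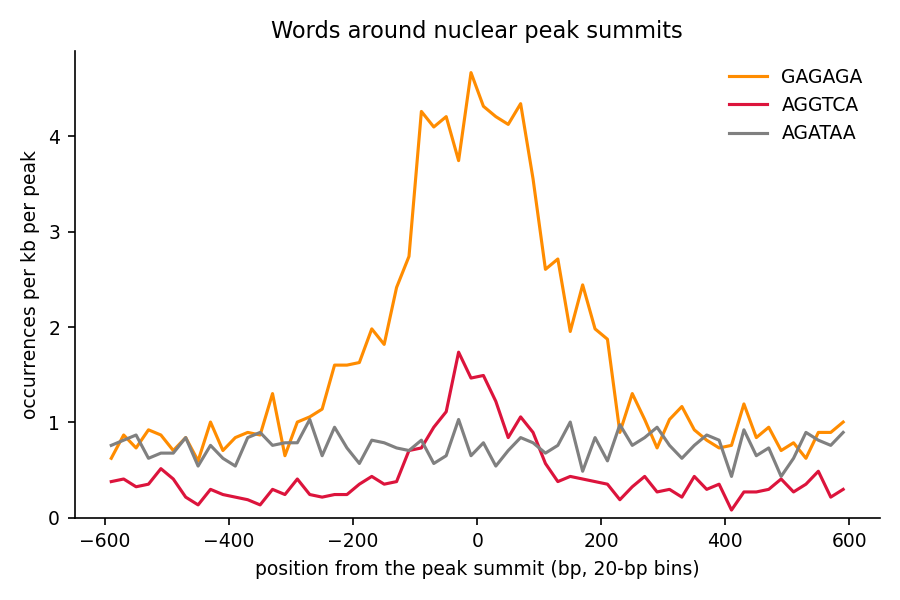
Occurrences of 3 planned words per kb per peak around 1843 nuclear summits, in bins of 20 bp from 600 bp to the left to 600 bp to the right of the summit. GAGAGA (orange) and AGGTCA (red) rise around the summit, while AGATAA (grey), present in 9.71% of summit windows and 9.98% of flanks, stays level.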

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

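The tests in this part were chosen after the result was seen. A signal appeared in data that the comparisons of nuclear regions do not use: 18 of the 1861 thresholded peaks lay on the mitochondrial chromosome, and the strongest peak of the whole list, with a signal of 2371, was among them.

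All 18 mitochondrial candidate regions of the series list passed the threshold, against 6.15% of nuclear candidates, and they covered 37.1% of the mitochondrial chromosome, against 0.626% of the nuclear genome. This breadth is consistent with mitochondrial DNA that was more abundant in the ChIP libraries than in the control. AGGTCA does not account for these peaks, since 0 of 18 summits held the word. The nuclear share gives 3.11 (p = 0.0331, one-sided exact binomial test, with summits so close together that they are not independent). That p cannot tell binding from base composition. The chromosome has 23.8% G and C, against 45.4% at nuclear summits, and holds the word only 2 times, so a count near 0 was likely wherever summits fell. Mitochondrial regions ranked higher in replicate 2, with a median rank of 20.5 against 155 in replicate 1; the median log2 ratio of ranks was −2.33, outside the middle 95% of medians of random nuclear peaks, −0.47 to 0.62, which may reflect a content of mitochondrial DNA that differed between the preparations. Mitochondrial read numbers of the ChIP and control libraries would settle this and were not analysed here.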

How the results depend on the processing

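Controls matched for GC content, peaks split by AGGTCA, the central part of chromosomes and transcript 5′ ends were chosen after seeing the data. The alternative of the strongest regions of the series list gave the thresholded list itself, so it says nothing and is in no count here. In the other alternatives run, the promoter share (10 alternatives, 1.24 to 2.51 times the reference), the X against autosome difference (11, odds ratio 1.34 to 2.28), the AGGTCA excess (10, 2.26 to 6.43 times) and the replicate overlap (6, 56.3 to 78.7%) kept their direction and their side of the threshold. The X odds ratio was 1.34 and 1.99 with each replicate alone and 1.47 in the central part of the chromosomes. Removing weaker peaks left 930 by construction. The number of gene lists called, 11, became 7 with the 930 strongest peaks, 6 with the window of 500 bp upstream and 100 bp downstream, 7 with the background of genes that have a candidate region and 4 with only the peaks that hold AGGTCA; the first and last of these use fewer peaks, and for the others the cause was not tested. With each replicate alone it was 9. Words called fell from 1214 to 583 against GC-matched candidate regions; this control changes the regions compared and the test as well as the GC content, and the cause was not tested. With only AGGTCA peaks the odds ratio was 0 for ribosomal protein, heat shock, early lineage and sex determination genes, of which none was bound by such a peak. For single lists, 239 results in alternatives stayed on the same side, 33 lost the call, among them these 4, and 1, bHLH factors in the wider window, gained it. The 239 take in lists that were not called at first and stayed uncalled, while the 33 all fall on the 11 called lists. The 239 therefore overstate how stable the calls were. No alternative set before the data were examined ended the call for ribosomal proteins, cell cycle, heat shock proteins, histones, Wnt signalling or chemoreceptors, but the size of the difference moved. With the background of genes that have a candidate region the odds ratio became 5.42 for ribosomal proteins, 3.57 for Wnt signalling and 0.206 for chemoreceptors. With each summit given to its nearest gene only it became 6.42 for ribosomal proteins (14 of 80 bound), 6.64 for heat shock proteins (4 of 22), 3.23 for histones and 0.0445 for chemoreceptors. For cell cycle genes it ran from 5.86 to 22.7. No paired analysis was possible because the series had 1 group. Depth is unknown, so how it limits the weaker peaks could not be measured.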

Other observations

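The tests of the nhr-2 locus, of AGGTCA, GC content and gene bodies across gene lists, of the share of peaks with paired words, of dense windows, of RNA gene types and of word variants were chosen after the data had been seen, as were the genes named in this paragraph. Some stretches of the genome carried runs of peaks. The densest window of 20 kb, on chromosome V from 11940001 to 11960000, held 9 thresholded summits around F58H1.5 and F58H1.6, and the next, from 1560001 to 1580000 on the same chromosome, held 8 around cdc-25.2, which encodes a CDC25 phosphatase that activates cyclin-dependent kinases. Windows with 7 summits included those at plk-2, a polo-like kinase, at egl-27, a chromatin factor related to metastasis-associated proteins, and at cki-1 and cki-2. In 1000 uniform placements of the same number of summits per chromosome, the fullest window held 7 at most and 4 in the median; uniform placement ignores where open chromatin lies. Within 5 kb of cdc-25.2 there were 8 peaks, 3 with AGGTCA and the strongest with a signal of 228, although none lay in its promoter window, and cyd-1 had 6.

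Noncoding RNA genes of the unspecified ncRNA type held 160 of 1843 nuclear summits (8.68%, 7.44 to 10.1%). In a sample of 2814 of the 28139 other nuclear candidate regions the share was 1.67% (adjusted p = 1.18e-28, two-sided Fisher exact test over 7 RNA types). Transfer RNA genes held 6 summits, or 0.326%, against 0.355% (Fisher exact adjusted p = 1). Among single changes of the core word, GGGTCA and CGGTCA had the largest excess, with ratios of 2.89 and 2.21: GGGTCA lay in 12.4% of summits against 4.29% of GC-matched candidate regions, CGGTCA in 10.4% against 4.72% and TGGTCA in 8.79% against 5.64%, all with an adjusted p of 0.000647 or lower over 19 words, the core word among them (two-sided Fisher exact test). Changes at other positions matched TGGTCA, whose ratio was 1.56: ACGTCA lay in 10.3% against 6.51% (ratio 1.58), AGGACA in 9.50% against 5.97% (1.59) and AGGTGA in 10.7% against 6.67% (1.60), each with a Fisher exact adjusted p of 0.000202 or lower, and AGGTTA, ATGTCA, AGGGCA and AGGTCG were also higher (adjusted p from 0.00590 to 0.0453). Changes in position 3 gave no excess: AGATCA lay in 5.70% against 6.57% (Fisher exact adjusted p = 0.411), AGTTCA in 5.59% against 6.02% (adjusted p = 0.695), and AGCTCA was less frequent, at 2.77% against 6.51% (adjusted p = 3.28e-07).

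The strongest nuclear peaks lay at nhr-2. The peak at 5822097, which lies between those at 5821303 and 5822750, had a signal of 234. The weaker of these neighbours had 4.74 times as much (3.44 times in replicate 1 and 7.37 times in replicate 2). The 3 strongest peaks were set apart first, so a ratio above 1 was built in. Its size in both replicates argues against an even rise of signal along the transgene copies as the whole cause at these peaks. The lists hold only called regions, so signal between them could not be seen. The locus summits held AGGTCA in 4 of 5 cases (p = 0.0187, one-sided exact binomial test at 26.2%, the share of the 461 strongest nuclear peaks, among which 4 of the 5 are; summits so close together are not independent), which is consistent with binding of NHR-2 near its own gene. The strongest signal there was 2.67 times the strongest nuclear signal elsewhere, and whether extra copies of bound sequence raised it cannot be told apart from binding at the native gene, because the lists do not separate the copies.

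AGGTCA was unevenly spread over the peaks of the 8 lists bound more often. It lay at 0 of 25 ribosomal protein peaks, 0 of 8 heat shock peaks, 0 of 6 early lineage peaks, 0 of 4 sex determination peaks and 1 of 7 histone peaks, and at 4 of 10 cell cycle peaks, 3 of 8 Wnt peaks and 4 of 12 homeodomain peaks. An equal share in every list is argued against (p = 0.0118, permutation test over 76 peaks), although no list alone passed (lowest adjusted p = 0.186, for ribosomal proteins, two-sided Fisher exact test). GC content as the whole cause is argued against, since the shares still differed when the word was permuted among peaks of like GC content (permutation p = 0.0104). Peak signal, with which the share of the word rose, was not held equal between the lists. The 40 promoter peaks of ribosomal protein, heat shock and histone genes had a median signal of 83.4, against 72.8 for other promoter peaks. Their strongest had 187, while the strongest cell cycle promoter peaks had 281 to 417. Any part of signal in the differences between lists was not tested. Signal from transcribed gene bodies was examined over the 174 members of the ribosomal protein, heat shock and histone lists, bound or not. Their bodies held 0.252 series candidate summits per kb and the 1 kb upstream of them 0.900 (ratio 0.280, p = 5.48e-13, two-sided exact binomial test). These lists had been called for summits in a window that lies mostly upstream. Their 40 promoter peaks were all upstream and are among the upstream summits counted, so part of this excess was built in. Other genes were not compared. The ratio shows where candidate summits of these genes lay and cannot decide whether transcribed bodies added signal. NHR-2 may reach promoters such as those of ribosomal protein genes without the word, or they may give signal in any such experiment; another factor or an untagged strain would be needed and was not analysed here, and no biological explanation was tested.

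Regions strong in a single replicate differed in kind. The test of AGGTCA was set before its result was seen, and those of promoters and X were added beside it. Among the 1861 strongest regions of each replicate, 383 nuclear regions of replicate 1 overlapped none of the 3000 strongest of replicate 2, and 350 of replicate 2 none of the 3000 strongest of replicate 1. AGGTCA lay at 15.9% (12.4 to 20%) of the former and at 5.14% (3.08 to 8.01%) of the latter (p = 2.19e-06, two-sided Fisher exact test). Regions of replicate 2 alone were more often in promoters, 56.3% against 38.4% (Fisher exact adjusted p = 3.28e-06), and less often on X, 15.4% against 25.6% (adjusted p = 0.000729). With 1 library on each side, this compares the libraries only, and the cause of the difference was not tested.

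A further hypothesis, written before its test, was that paired core words at a preferred spacing mark the peaks. RGGTCA, with A or G in position 1, lay at 27.9% of summits and 10.6% of GC-matched regions. Over 48 arrangements of orientation and spacer up to 15 bases, no arrangement was found in more than 2 peaks, and the lowest adjusted p was 1 (two-sided Fisher exact test). Pairs of these spacings lay in 16 peaks, against 2 matched regions: 0.868% of all peaks (0.497 to 1.41%) and 3.11% of the 515 peaks with the word (1.79 to 4.996%). This argues against pairs of 2 exact RGGTCA words as the mark of the peaks or of most peaks with the word. Pairs with a changed word on 1 side were not counted, although changed words such as CGGTCA and AGGTGA were in excess. Whether most peaks hold such looser pairs is therefore left open. The 16 are too few to show whether they prefer a spacing, since no arrangement with at most 2 peaks could have passed.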
